A study of Homo sapiens with 20 samples.

How the data were processed

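ChIP-seq was measured in 20 libraries of auxin-inducible CTCF degron HCT116 cells: 2 libraries for each of CTCF, SMC1, phosphorylated Pol II, H3K27ac and input DNA in each of 2 conditions, untreated or given 500 µM auxin for 6 h. Per the labels' protocols, fixed and sonicated chromatin was immunoprecipitated, and tagmentation-based libraries were sequenced in paired-end mode. The submitters' processing notes name the hg19 genome build, BWA 0.7.17, Picard 2.18.23, MACS2 2.2.7.1 and deepTools 3.4.3, without the role or settings of each. The peak threshold, the use of the input libraries, any filter on blacklisted regions and the way the 2 replicates were combined are not given in the sources used here.

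The authors deposited 8 peak lists, 1 per antibody and condition. Each gives a chromosome, a start and an end, and the CTCF and H3K27ac lists add a running peak name. No height, fold enrichment or p-value column is present, so peak width stood in for peak strength, a choice fixed for that case before the data were examined. Peaks within a list did not overlap. Since a list is a set of calls that passed a threshold, its length moves with depth, enrichment and background as well as with binding, and a peak that is absent from a list may lie just under the threshold. Without counts, neither the depth per library nor a replicate error could be given. Values between conditions therefore have no test.

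Chromosomes 1 to 22 and X were analysed, and the few peaks on Y were left out. Peaks were compared with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. A peak counted as shared when at least 1 bp overlapped. Percentages have 95% Wilson intervals, and intervals from a bootstrap of 5 Mb genome blocks (1000 draws), both of which cover the sampling of peaks or blocks only. In the text an interval after a percentage or odds ratio is the block bootstrap one unless another is named. Each of 12 associations between kinds of peak was tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 12, and was called when the adjusted p was under 0.05 and the bootstrap interval of the odds ratio excluded 1. Odds ratios stratified by quintiles of peak width used the Mantel-Haenszel method in statsmodels 0.14.6, and their intervals are those of that method. Several p-values were too small for the software to represent and are not printed. For 3 further comparisons of SMC1 classes, chosen after the retained share of each class had been seen, p was adjusted over those 3. All 16 pairs of lists examined overlapped more than in any of 1000 circular shifts within each chromosome. The span of a chromosome was taken up to the last peak in any list, so assembly gaps were not excluded, which lowers the overlap of shifted peaks.

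The peaks named were the widest 5 lost and the widest 5 gained of each antibody. Of the 1 Mb windows with at least 20 untreated peaks, the 3 with the highest and the 3 with the lowest retained share were named for each antibody, with ties taken in chromosome order. Positions are 1-based.

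The code was tested on simulated data. Overlaps matched a brute-force count, the bootstrap interval covered a known odds ratio in 187 of 200 simulated sets of 3000 peaks, and 3 of 200 sets with unrelated labels were called. An association made only by width had an odds ratio of 2.09, and 0.997 after stratification.

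Alternatives fixed in advance were 50% reciprocal overlap, a gap of up to 1 kb, the part of a list above its median width, merging of peaks within 1 kb, all sequences, stratification by width, direct overlap or 50 kb in place of 10 kb, and random placement in place of shifts. Leaving out chromosomes 8, 10 and 17, and leaving out peaks that overlapped a peak of each of the other antibodies in the same condition, were added after seeing the data. The latter removes peaks in each condition separately, so the partner of a removed peak then counts as lost or gained. A planned analysis of promoters, of gene lists and of the CTCF motif needs an hg19 annotation and sequence, which were not used here, so no gene is named.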

Results

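Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed in HCT116, a human colorectal carcinoma cell line engineered so that auxin triggers degradation of CTCF, the zinc-finger protein that anchors chromatin loops and domain boundaries. Cells were left untreated or given 500 µM auxin (indole-3-acetic acid) for 6 h. Immunoprecipitation was directed at CTCF, at SMC1, a core subunit of the cohesin ring that extrudes loops, at RNA polymerase II phosphorylated on the C-terminal domain of its Rpb1 subunit (Pol II), and at H3K27ac, the histone acetylation found at active promoters and enhancers. Each of the 8 combinations of antibody and condition had 2 libraries, and 4 input DNA libraries completed the set of 20. The values analysed were 1 deposited peak list per combination, without peak heights or read depth, so the depth of each library is unknown and no difference between conditions has a replicate error. Peaks are described by hg19 position, and genes at the peaks were not analysed here. A peak present in both conditions is called retained, an untreated peak without an overlapping auxin peak lost, and an auxin peak without an overlapping untreated peak gained.

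The first comparison asked how much of the CTCF map remained after CTCF degradation. The CTCF list held 32102 peaks covering 34.5 Mb in untreated cells and 11058 peaks covering 10.2 Mb after auxin, a ratio of 0.344. Of the untreated peaks, 10610 (33.1%, 95% block bootstrap interval 32.4 to 33.7) were retained and 21492 were lost, while 277 of the auxin peaks (2.505%, 2.06 to 3.01) were gained. Retained CTCF peaks had a median width of 1468 bp in the untreated list and lost peaks 677 bp. In the auxin list, peaks that overlapped an untreated peak had a median width of 758 bp. They covered 10.1 Mb, against 16.9 Mb for retained peaks in the untreated list. Retained CTCF peaks were thus still listed, but narrower by the median. The same medians, untreated and auxin, were 648 and 591 bp for SMC1, 1307 and 1152.5 bp for H3K27ac, and 1068 and 1258 bp for Pol II. In the widest quintile of untreated CTCF peaks 72.3% were retained, against 2.69% in the narrowest. The widest lost CTCF peaks lay at chromosome 8, 104786387 to 104790712 (4326 bp), chromosome 12, 21447832 to 21451965 (4134 bp), chromosome 7, 21292745 to 21296855 (4111 bp), chromosome 8, 104805891 to 104809955 (4065 bp) and chromosome 18, 61514390 to 61518433 (4044 bp). None of these 5 sites overlapped an H3K27ac or Pol II peak in either condition, and all but the first overlapped an untreated SMC1 peak. The widest gained CTCF peaks were narrower and lay at chromosome 17, 63965719 to 63966942 (1224 bp) and 48100635 to 48101773 (1139 bp), chromosome 1, 165564557 to 165565744 (1188 bp), and chromosome 21, 11061371 to 11062460 (1090 bp) and 10538630 to 10539705 (1076 bp). The retained share was 18.8% when both peaks had to share 50% of their length, a rule under which 45.45% of auxin CTCF peaks counted as gained, and 55.0% above the median width, where 0.398% were gained. The gained share was 1.41% with a gap of up to 1 kb, 1.40% with peaks within 1 kb merged and 6.41% without peaks shared by all 4 antibodies.

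**Figure D1:**
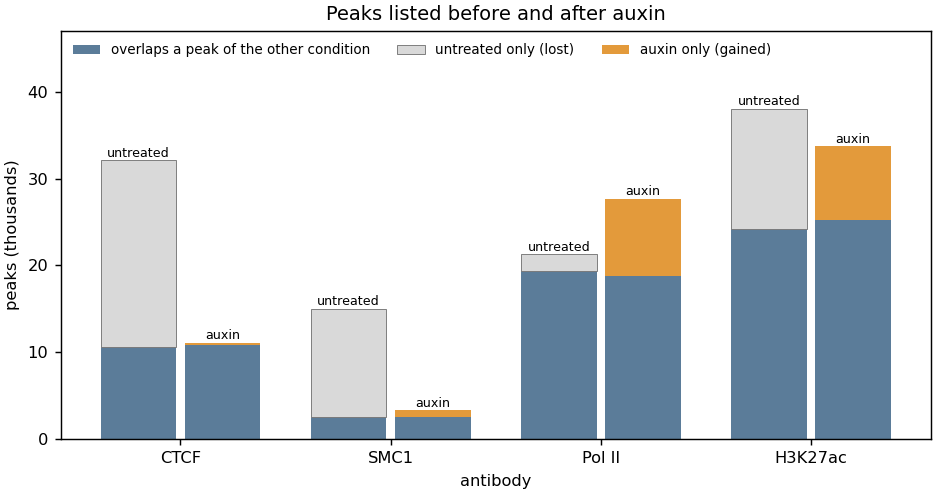
Number of peaks (vertical axis, in units of 1000) in the untreated and auxin lists of each antibody on chromosomes 1 to 22 and X, split into peaks that overlapped a peak of the other condition by at least 1 bp and peaks found in 1 condition only. CTCF went from 32102 to 11058 peaks and SMC1 from 14996 to 3289, whereas Pol II went from 21298 to 27697 and H3K27ac from 38052 to 33752.

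CTCF sites that also carried cohesin were retained more often than the others. In untreated cells 12484 CTCF peaks (38.9%) overlapped an SMC1 peak, 45.5 times the mean of 1000 circular shifts of the peaks along each chromosome (one-sided permutation p = 0.001, the smallest these shifts can give). Of these cohesin-bearing CTCF peaks 70.4% were retained, against 9.27% of the 19618 CTCF peaks without SMC1 (odds ratio 23.3, block bootstrap interval 21.7 to 25.1). The odds ratio was 10.8 stratified by quintiles of peak width, 11.9 above the median width and 12.3 with 50% reciprocal overlap. Overlap with H3K27ac separated CTCF peaks little: 35.6% of the 3698 CTCF peaks at H3K27ac were retained and 32.7% of the 28404 others (odds ratio 1.14, 1.05 to 1.23, Fisher's exact test, adjusted p = 0.000497). That small difference was not significant with a gap of up to 1 kb (odds ratio 1.03) or with 50% reciprocal overlap (1.04), and the odds ratio was 0.788 when peaks shared by all 4 antibodies were left out, a setting that counts partners of removed peaks as lost. Peaks are not replicates, so these tests compare kinds of peak within the deposited lists.

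Among the 315 windows of 1 Mb with at least 20 untreated CTCF peaks, the median retained share was 36.4%. The highest shares were found at chromosome 1, 20 to 21 Mb (16 of 22 peaks, 72.7%), chromosome 1, 111 to 112 Mb (14 of 21) and chromosome 19, 51 to 52 Mb (15 of 23). The lowest were at chromosome 4, 155 to 156 Mb (2 of 21 peaks, 9.52%), chromosome 17, 40 to 41 Mb (2 of 20) and chromosome 2, 175 to 176 Mb (3 of 23). In the chromosome 17 window, where 2 of 20 CTCF peaks were retained, 24 of 26 Pol II peaks and 21 of 27 H3K27ac peaks were retained.

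The second comparison addressed cohesin. The SMC1 list went from 14996 peaks (8.87 Mb) to 3289 peaks (2.198 Mb), a ratio of 0.219, and 2557 of the untreated peaks (17.1%, 16.0 to 18.0) were retained. In untreated cells 84.3% of SMC1 peaks overlapped a CTCF peak, 22.96% an H3K27ac peak and 14.8% a Pol II peak. After auxin 34.6% overlapped an auxin CTCF peak, 58.0% an H3K27ac peak and 42.3% a Pol II peak of the same condition. The overlap of SMC1 with H3K27ac was 8.55 times that of shifted peaks in untreated cells and 23.5 times after auxin, and with Pol II it was 10.1 and 21.99 times (one-sided permutation p = 0.001 for each, the smallest these shifts can give). For CTCF peaks on SMC1 the ratio to shifted peaks was also higher after auxin, 56.3 against 45.5 in untreated cells. The share of SMC1 peaks at CTCF thus fell against a CTCF list that had itself shortened.

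**Figure D2:**
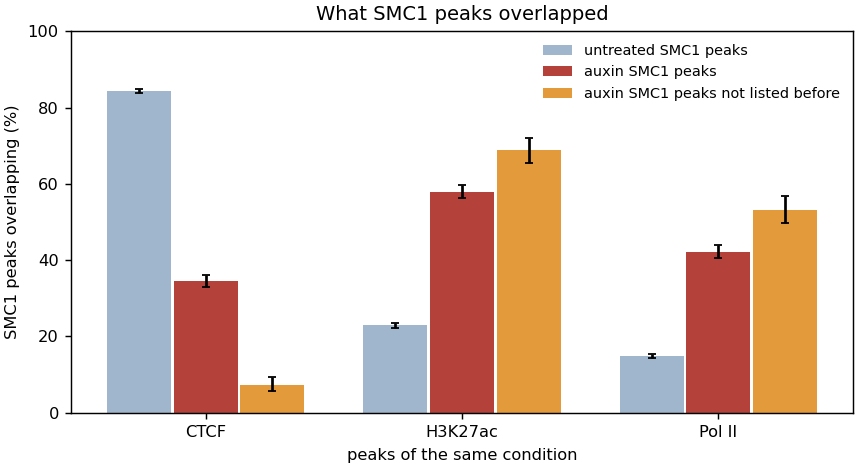
Percent of SMC1 peaks (vertical axis) that overlapped CTCF, H3K27ac or Pol II peaks of the same condition, for untreated SMC1 peaks, auxin SMC1 peaks, and auxin SMC1 peaks not listed before, with 95% Wilson intervals. Overlap with CTCF was 84.3%, 34.6% and 7.30% in that order, and overlap with H3K27ac was 22.96%, 58.0% and 68.8%.

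SMC1 peaks at CTCF sites were retained less often than other SMC1 peaks. Of 12642 SMC1 peaks at CTCF, 9.37% were retained, against 58.3% of the 2354 SMC1 peaks without CTCF (odds ratio 0.0741, 0.0667 to 0.0819). Where the CTCF peak itself was lost, 108 of 3713 SMC1 peaks (2.91%) were retained. Where the CTCF peak was retained, 1077 of 8929 SMC1 peaks (12.1%) were retained (odds ratio 4.56, 3.69 to 5.83, Fisher's exact test across peaks, adjusted p = 1.16e-69). Of the 12439 lost SMC1 peaks 92.1% overlapped an untreated CTCF peak, and 62.7% overlapped an auxin CTCF peak. A retained CTCF peak is one still listed, and the median width of such peaks was lower after auxin. The odds ratio for retained against lost CTCF was 3.07 above the median width, 3.29 with a gap of up to 1 kb, 3.78 stratified by width, 8.20 without peaks shared by all 4 antibodies and 9.43 with 50% reciprocal overlap.

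Overlap with active chromatin went with retention in the opposite direction. SMC1 peaks at H3K27ac were retained in 41.3% of 3443 cases and the others in 9.83% of 11553 (odds ratio 6.44, 5.80 to 7.15). At Pol II the shares were 39.6% of 2220 and 13.1% of 12776 (odds ratio 4.35, 3.81 to 4.97, adjusted p = 1.61e-171 by Fisher's exact test), and the odds ratio ranged from 3.91 with 50% reciprocal overlap to 6.81 without peaks shared by all 4 antibodies. Classes that combine CTCF and H3K27ac were compared after the values were seen. SMC1 peaks at a lost CTCF peak without H3K27ac were retained in 16 of 3161 cases (0.506%), and those at a lost CTCF peak with H3K27ac in 92 of 552 (16.7%). At a retained CTCF peak the shares were 892 of 7965 (11.2%) without H3K27ac and 185 of 964 (19.2%) with it. SMC1 peaks at H3K27ac without CTCF were retained in 1144 of 1927 cases (59.4%), and those with neither mark in 228 of 427 (53.4%). Where SMC1 lacked CTCF, Pol II separated the peaks little. Retention there was 60.8% of 1119 with H3K27ac and Pol II, 57.4% of 808 with H3K27ac only and 53.2% of 412 with none of the marks. With CTCF it was 20.95% of 740 with H3K27ac and Pol II, and 8.09% of 10780 with neither. Among SMC1 peaks without CTCF the odds ratio for H3K27ac was 1.27 (1.03 to 1.58, Fisher's exact test, adjusted p = 0.0261). Among those with CTCF it was 2.52 (18.3% against 8.16%, 2.14 to 2.95, Fisher's exact test, adjusted p = 2.11e-30), and the difference between these odds ratios was not tested.

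**Figure D3:**
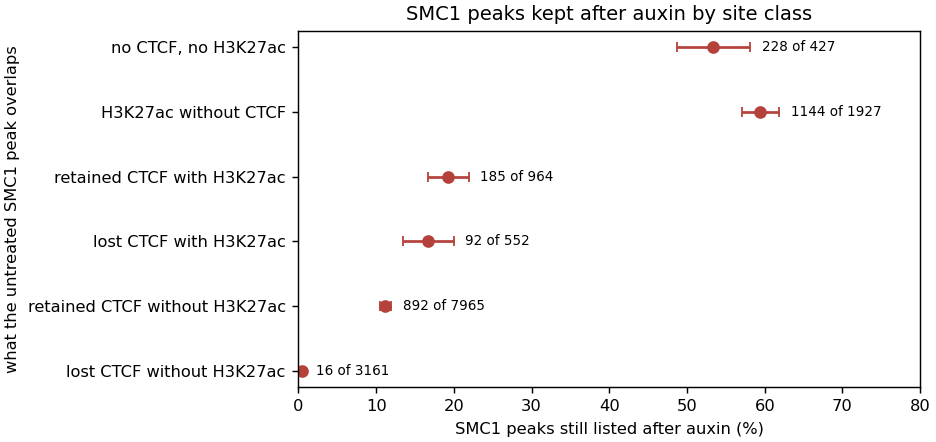
Percent of untreated SMC1 peaks still listed after auxin (horizontal axis) by what the untreated peak overlapped, with 95% block bootstrap intervals and the number of retained peaks of all peaks in the class. Peaks at a lost CTCF peak without H3K27ac lie at 0.506%, and peaks without CTCF lie at 53.4% and 59.4%.

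Auxin SMC1 peaks that were not listed before numbered 753 (22.9% of the auxin list, 21.2 to 24.5). Of these gained SMC1 peaks 68.8% overlapped an auxin H3K27ac peak, 53.3% an auxin Pol II peak and 7.30% an auxin CTCF peak. The widest 5 lay at chromosome 10, 63658024 to 63660909 (2886 bp), chromosome 1, 84767134 to 84769768 (2635 bp), chromosome 17, 39677312 to 39679518 (2207 bp), chromosome 7, 92466527 to 92468618 (2092 bp) and chromosome 8, 94939211 to 94941107 (1897 bp). All 5 overlapped H3K27ac in both conditions and Pol II after auxin, and none overlapped CTCF. The widest lost SMC1 peaks differed in CTCF: those at chromosome 1, 192987000 to 192990148 (3149 bp), chromosome 10, 111896242 to 111898833 (2592 bp), chromosome 5, 96497031 to 96499536 (2506 bp), chromosome 10, 91552968 to 91555470 (2503 bp) and chromosome 8, 126241877 to 126244169 (2293 bp) all overlapped CTCF peaks before and after auxin. Active marks occurred there too. The lost peaks of 3149, 2503 and 2293 bp overlapped H3K27ac in both conditions, and those of 3149 and 2506 bp overlapped Pol II after auxin. Under the 50% rule the gained share of the auxin SMC1 list was 35.1%.

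In the 21 windows of 1 Mb with at least 20 untreated SMC1 peaks, retention was highest at chromosome 8, 126 to 127 Mb (22 of 32 peaks, 68.8%), chromosome 17, 57 to 58 Mb (14 of 22, 63.6%) and chromosome 8, 94 to 95 Mb (13 of 22, 59.1%). All 3 lie on chromosomes 8 and 17, where 22.8% and 22.2% of all SMC1 peaks were retained. These windows held 87, 85 and 49 untreated H3K27ac peaks, and the 3 windows with the lowest retention, which follow, held 23, 51 and 31. At chromosome 12, 54 to 55 Mb, 0 of 23 SMC1 peaks were retained, which allows a share of up to 13.0% counted as 3 of 23 peaks and 14.3% as the Wilson bound, although 21 of 34 CTCF peaks (61.8%) and 19 of 23 H3K27ac peaks were retained there. The next lowest were chromosome 19, 47 to 48 Mb (2 of 21 SMC1 peaks, with 21 of 41 CTCF peaks retained) and chromosome 1, 27 to 28 Mb (2 of 20 SMC1 peaks, with 15 of 30 CTCF peaks retained).

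**Figure D4:**
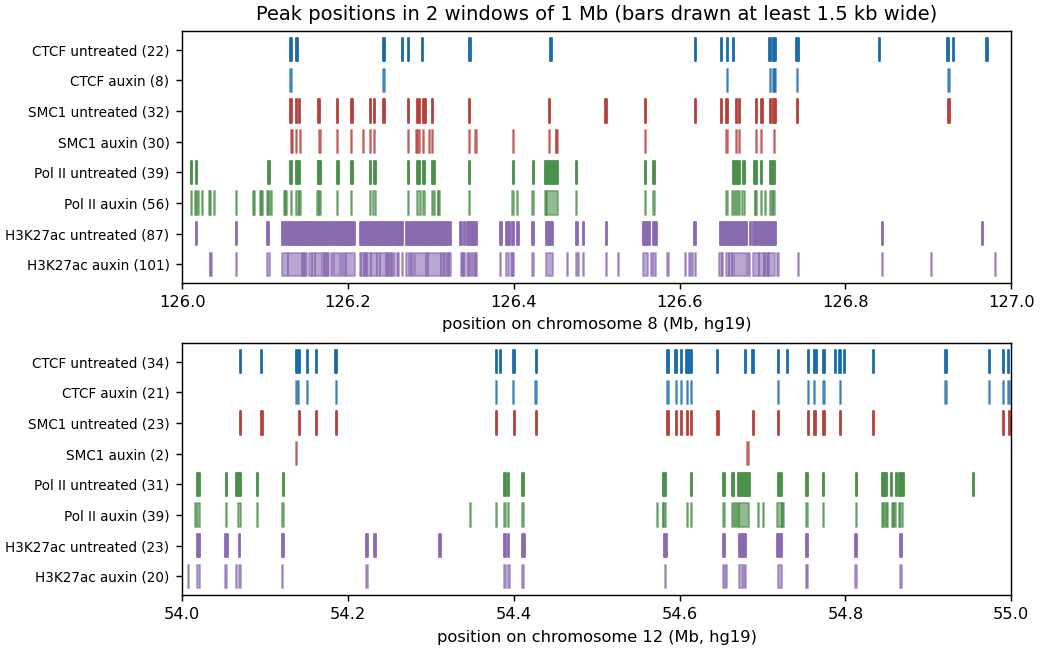
Positions (horizontal axis, Mb, hg19) of the peaks of all 8 lists in the windows with the highest and the lowest SMC1 retention, chromosome 8, 126 to 127 Mb, and chromosome 12, 54 to 55 Mb, with the number of peaks per list in parentheses and each bar drawn at least 1.5 kb wide. The chromosome 8 window kept 22 of 32 SMC1 peaks, and the chromosome 12 window kept 0 of 23.

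The third comparison concerned transcribing polymerase. Pol II peaks were largely in place after auxin: 19388 of 21298 untreated peaks (91.0%, 90.5 to 91.6) were retained and 1910 lost. The auxin list was longer, with 27697 peaks, of which 8970 (32.4%, 31.7 to 33.2) were gained. Gained Pol II peaks were narrow, with a median of 539 bp against 1258 bp for the other auxin peaks, and 30.9% of them overlapped an auxin H3K27ac peak, against 68.1% of the others. Of the widest quintile of untreated Pol II peaks 99.9% were retained, and 2.22% of the widest quintile of auxin peaks were gained. The widest gained Pol II peaks lay at chromosome 9, 21519075 to 21526847 (7773 bp) and 21848365 to 21854799 (6435 bp), chromosome 6, 130683732 to 130689961 (6230 bp), chromosome 7, 83810157 to 83814003 (3847 bp) and chromosome 3, 156522065 to 156525888 (3824 bp). The widest lost Pol II peaks lay at chromosome 1, 173016644 to 173020763 (4120 bp), chromosome 8, 6432604 to 6435529 (2926 bp), chromosome 19, 18686995 to 18689641 (2647 bp), chromosome 1, 109941713 to 109944145 (2433 bp) and chromosome 10, 54202526 to 54204736 (2211 bp). Of the 280 windows with at least 20 untreated Pol II peaks, 47 kept all of them, among them chromosome 1, 6 to 7 Mb (20 of 20), 11 to 12 Mb (23 of 23) and 26 to 27 Mb (28 of 28), and the lowest shares were 14 of 20 at chromosome 6, 99 to 100 Mb, 15 of 21 at chromosome 1, 113 to 114 Mb, and 18 of 25 at chromosome 12, 10 to 11 Mb. Above the median width, 9.82% of auxin Pol II peaks were gained.

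Pol II changes were not concentrated at lost CTCF sites. Of lost Pol II peaks 28.1% lay within 10 kb of a lost CTCF peak, against 32.0% of retained peaks (odds ratio 0.832, 0.747 to 0.925, Fisher's exact test across peaks, adjusted p = 0.000497). Of gained Pol II peaks 27.9% did so, against 32.2% of the other auxin peaks (odds ratio 0.814, 0.768 to 0.861, Fisher's exact test, adjusted p = 3.75e-13). The first difference was not significant stratified by width (odds ratio 0.908, 0.813 to 1.015), within 50 kb (0.936), with 50% reciprocal overlap (0.995) or above the median width (0.711), and the second was not significant above the median width (0.981). With direct overlap in place of 10 kb the odds ratios were 0.452 and 0.308, not stratified by width although the changed peaks were narrower. An auxin CTCF peak was overlapped by 4.61% of lost and 4.64% of retained Pol II peaks. Gained Pol II peaks did so in 2.79% of cases and the other auxin peaks in 4.87%. By direct overlap, gained peaks were thus less frequent at auxin CTCF peaks too, while lost peaks showed no such difference there. Whether the deficit was larger at lost CTCF was not tested, nor was nearness within 10 kb of auxin CTCF.

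**Figure D5:**
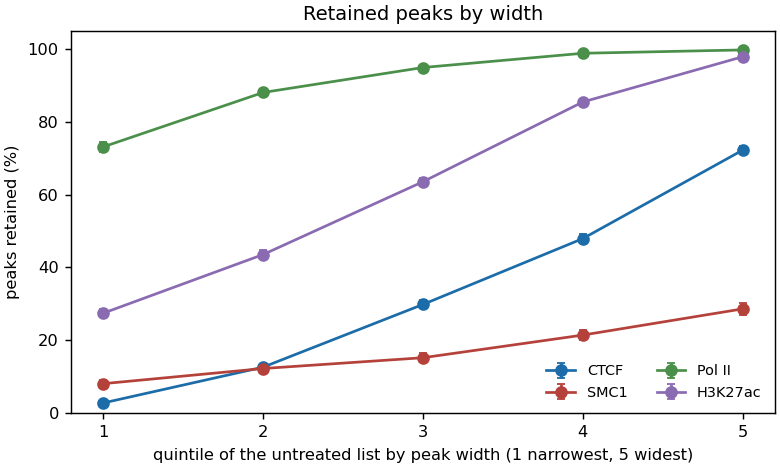
Percent of untreated peaks retained (vertical axis) in each quintile of the untreated list by peak width (horizontal axis, from narrowest to widest), with 95% Wilson intervals that are mostly smaller than the symbols. Pol II ranged from 73.2% to 99.9%, H3K27ac from 27.4% to 98.0%, CTCF from 2.69% to 72.3% and SMC1 from 8% to 28.6%.

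The last comparison concerned active chromatin. The H3K27ac list held 38052 peaks (54.8 Mb) in untreated cells and 33752 (47.6 Mb) after auxin. Of the untreated peaks 24205 (63.6%, 62.2 to 65.0) were retained and 13847 lost, and 8484 auxin peaks (25.1%, 24.4 to 25.9) were gained. Lost H3K27ac peaks were narrow (median 551 bp against 1307 bp for retained peaks) and 10.7% of them overlapped an untreated Pol II peak, against 52.98% of retained peaks. The widest lost H3K27ac peak, at chromosome 11, 34910315 to 34917577 (7263 bp), overlapped an untreated CTCF and an untreated SMC1 peak and neither after auxin. Other wide lost peaks lay at chromosome 6, 130746381 to 130751332 (4952 bp), chromosome 4, 98315131 to 98319161 (4031 bp), chromosome 1, 172793555 to 172797361 (3807 bp) and chromosome 15, 71729714 to 71733459 (3746 bp). None of these 5 lost H3K27ac peaks overlapped a Pol II peak in either condition. The widest gained H3K27ac peaks were at chromosome 11, 6340808 to 6344038 (3231 bp), chromosome 6, 111871660 to 111874715 (3056 bp), chromosome 7, 129463990 to 129467018 (3029 bp), chromosome 17, 17723877 to 17726879 (3003 bp) and chromosome 16, 25162103 to 25164891 (2789 bp). Under the 50% rule 43.2% of auxin H3K27ac peaks were gained, and above the median width 6.20% were.

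H3K27ac retention was lowest at chromosome 8, 88 to 89 Mb (11 of 62 peaks, 17.7%), chromosome 6, 77 to 78 Mb (4 of 20) and chromosome 5, 45 to 46 Mb (8 of 35), windows that held 0, 0 and 1 untreated Pol II peaks. It was highest at chromosome 19, 36 to 37 Mb (21 of 21), chromosome 17, 79 to 80 Mb (30 of 31) and chromosome 19, 41 to 42 Mb (28 of 29). As for Pol II, peaks that changed were less often close to lost CTCF. Of lost H3K27ac peaks 22.3% lay within 10 kb of a lost CTCF peak and of retained peaks 28.1% (odds ratio 0.735, 0.691 to 0.776, Fisher's exact test, adjusted p = 2.02e-35). Of gained H3K27ac peaks 23.6% lay that close, against 27.7% of the other auxin peaks (odds ratio 0.807, 0.757 to 0.854), a difference that was not significant stratified by width (0.967, 0.905 to 1.03) or above the median width (0.905). With direct overlap in place of 10 kb the odds ratios were 0.465 and 0.499, not stratified by width although the changed peaks were narrower. By direct overlap, lost peaks were less frequent at auxin CTCF peaks too, with 2.07% of them and 3.85% of retained peaks overlapping one. Whether the deficit was larger at lost CTCF was not tested. For gained and other auxin H3K27ac peaks the shares overlapping an auxin CTCF peak differed little, 3.48% and 3.68%. Nearness within 10 kb of retained CTCF was not tested.

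Changes in Pol II and in H3K27ac coincided only in part. Lost Pol II peaks overlapped a lost H3K27ac peak in 9.01% of cases and retained Pol II peaks in 6.64% (odds ratio 1.39, 1.15 to 1.65, Fisher's exact test, adjusted p = 0.000205). The odds ratio was 1.67 stratified by width (1.389 to 1.998) and 1.92 with a gap of up to 1 kb, but 0.801 with 50% reciprocal overlap and 1.61, not significant, above the median width. An untreated H3K27ac peak of any kind was overlapped by 39.4% of lost and 68.3% of retained Pol II peaks. Of these, 172 of 753 lost and 1287 of 13239 retained Pol II peaks lay at a lost H3K27ac peak, a comparison that was not tested. Gained Pol II peaks overlapped a gained H3K27ac peak in 5.41% of cases and the other auxin Pol II peaks in 6.99% (odds ratio 0.761, 0.682 to 0.846, Fisher's exact test, adjusted p = 5.42e-07). This difference was not significant stratified by width (0.898, 0.792 to 1.02) or above the median width (0.936), and the odds ratio was 1.08 with a gap of up to 1 kb and 1.26 without peaks shared by all 4 antibodies, a setting that counts partners of removed peaks as gained. It also reflects that 30.9% of gained Pol II peaks overlapped any auxin H3K27ac peak, against 68.1% of the others. Among those that did, the direction was opposite: 17.5% of gained and 10.3% of other Pol II peaks lay at a gained H3K27ac peak (odds ratio 1.86, 1.65 to 2.09). That comparison was chosen after seeing the data.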

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

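No paired analysis was possible because 1 list per group was analysed, with none per replicate, and for the same reason no replicate could be left out. The promoter, motif and gene list alternatives were not run. The settings without chromosomes 8, 10 and 17 and without peaks shared by all 4 antibodies were chosen after seeing the data. With 50% reciprocal overlap, retained shares were 18.8% (CTCF), 14.2% (SMC1), 72.7% (Pol II) and 50.4% (H3K27ac), and gained shares 45.45%, 35.1%, 44.1% and 43.2% in the same order. With a gap of up to 1 kb they were 36.2%, 17.7%, 94.2% and 70.6% retained and 1.41%, 21.1%, 24.2% and 19.55% gained. Above the median width they were 55.0%, 23.2%, 98.9% and 87.3% retained and 0.398%, 16.1%, 9.82% and 6.20% gained. Merging peaks within 1 kb gave 35.05% (CTCF) and 92.1% (Pol II) retained, and 1.40% (CTCF), 28.05% (Pol II) and 26.3% (H3K27ac) gained. Without chromosomes 8, 10 and 17, 16.2% of SMC1 and 64.6% of H3K27ac peaks were retained, and 2.03% of CTCF and 31.7% of Pol II peaks gained. Without peaks shared by all 4 antibodies, 32.2% of CTCF and 62.8% of H3K27ac peaks were retained, and gained shares were 6.41% (CTCF), 25.7% (SMC1), 34.8% (Pol II) and 27.6% (H3K27ac). In that setting the partner of a removed peak counts as lost or gained by construction, also in the associations below. The other 17 shares stayed within the binomial interval.

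The 4 SMC1 associations, that of CTCF retention with SMC1 and that of lost H3K27ac near lost CTCF kept their direction and significance in every alternative run, and over all 12 associations 64 values did so. For SMC1 retention with H3K27ac the odds ratio ranged from 5.81 to 7.14. CTCF retention with H3K27ac had an odds ratio of 1.03 with a 1 kb gap and 1.04 with reciprocal overlap, neither significant, and 0.788 without shared peaks. Lost Pol II near lost CTCF was not significant within 50 kb (0.936), with reciprocal overlap (0.995), stratified by width (0.908) or above the median width (0.711). Gained Pol II near lost CTCF was not significant above the median width (0.981). Gained H3K27ac near lost CTCF was not significant stratified by width (0.967) or above the median width (0.905). Gained Pol II with gained H3K27ac was 1.08 with a 1 kb gap, 0.898 stratified and 0.936 above the median width, none significant, and 1.26 without shared peaks. Lost Pol II with lost H3K27ac was 0.801 with reciprocal overlap and 1.61, not significant, above the median width, where 122 lost peaks remained. Above the median width fewer peaks were tested, and for the other changes the cause was not tested. Random placement left all 16 overlaps between lists past the threshold. The depth of each list is unknown, so weak peaks cannot be told from absent ones.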

Other observations

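The tests of width, of chromosome 8, of domain width, of CTCF retention across windows and of gained SMC1 peaks were written before their result was seen, and for the correlation across windows with the share at H3K27ac no outcome was set in advance. The domain-width test among SMC1 peaks without CTCF was chosen after the retained shares by class and by domain width had been seen, though before its own value. The tests of CTCF as a control, of SMC1 peaks without and with CTCF, of the width of gained Pol II peaks and of their share at gained H3K27ac peaks were chosen after it, as was the comparison of Pol II peaks at H3K27ac, and the setting without chromosomes 8, 10 and 17 was added after seeing the data.

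Retained SMC1 followed broad H3K27ac. Of untreated SMC1 peaks at an H3K27ac peak under 1 kb wide 28.7% were retained (198 of 690), at 1 to 2 kb 30.3%, at 2 to 5 kb 41.1% and at 5 kb or more 59.1% (585 of 990). Across 437 windows of 1 Mb with at least 10 untreated peaks of both CTCF and SMC1, the retained share of SMC1 rose with the share of its peaks at H3K27ac (Pearson's r = 0.67, Spearman's rho = 0.63, permutation p = 1e-05 for both, the smallest 100000 permutations can give, adjusted p = 2e-05, r = 0.67 without the 2 windows farthest from the median). Windows are not independent replicates. The hypothesis that SMC1 retention of a window follows its CTCF retention was not borne out: rho was -0.19 and r -0.18 (permutation p = 4e-05 and 0.0001, adjusted p = 5e-05 and 0.0001, over 4 coefficients, r = -0.19 without the 2 farthest windows). These coefficients were not adjusted for the share of SMC1 peaks at H3K27ac. Across single peaks the relation was positive, with 12.1% of SMC1 peaks kept at retained and 2.91% at lost CTCF peaks.

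Gained SMC1 peaks overlapped gained Pol II peaks more often than other auxin SMC1 peaks did, but most gained SMC1 peaks overlapped none. Of 753 gained SMC1 peaks 15.5% overlapped a gained Pol II peak, against 6.66% of the other 2536 auxin SMC1 peaks (odds ratio 2.58, 1.98 to 3.33, Fisher's exact test, p = 1.03e-12, not stratified by width). The odds ratio also reflects that 401 of the 753 gained and 989 of the 2536 other peaks overlapped any auxin Pol II peak. Of these, 117 of 401 gained and 169 of 989 other SMC1 peaks lay at a gained Pol II peak, a comparison that was not tested. Of gained Pol II peaks 72.4% lay within 10 kb of an untreated Pol II peak, and of lost Pol II peaks 68.6% lay that close to a retained one. The windows with the most gained Pol II peaks were chromosome 17, 57 to 58 Mb (36 peaks), which was also among the windows with the highest SMC1 retention, and chromosome 9, 21 to 22 Mb (32 peaks), which held the widest gained Pol II peaks of the genome.

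The first pattern weighed is that SMC1 peaks at H3K27ac sites were kept more often than other SMC1 peaks. Of the 2557 retained SMC1 peaks 1421 (55.6%) overlapped an untreated H3K27ac peak, against 16.3% of lost ones, and 46.3% overlapped an untreated CTCF peak. The pattern therefore does not describe all kept peaks. Wider SMC1 peaks at H3K27ac are not the whole cause, since the odds ratio was 5.87 (5.35 to 6.45) within quintiles of width, nor are chromosomes 8, 10 and 17, without which it was 6.28. Peak strength itself stays open, since the lists hold no heights and width is only a stand-in. Whether background at active chromatin common to every antibody has a part stays open. CTCF retention with H3K27ac had an odds ratio of 1.14 (1.05 to 1.23) against 6.44 for SMC1. The SMC1 value includes peaks without CTCF, a class that the CTCF list cannot hold. For SMC1 peaks with CTCF, the closer match, it was 2.52 (2.14 to 2.95), above the CTCF value by a much smaller margin. Absence of CTCF at these sites is not the whole cause, since among SMC1 peaks with CTCF the odds ratio was 2.52 (2.14 to 2.95), or 1.90 within quintiles of width (1.64 to 2.22), and at lost CTCF peaks 16.7% of those with H3K27ac and 0.506% of those without were retained, but its part stays open, as without CTCF the odds ratio was 1.27 (1.03 to 1.58). Background of the SMC1 antibody itself stays open: 15.3% of the widest quintile of auxin H3K27ac peaks with Pol II carried an SMC1 peak, which decides neither way.

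Within it, a hypothesis is that cohesin is kept preferentially in wide H3K27ac domains. The odds ratio for domains of 5 kb or more was 2.64 (2.26 to 3.08) within quintiles of SMC1 width. Among SMC1 peaks at H3K27ac without CTCF it was 1.51 (1.22 to 1.88), so a lower share of CTCF sites in wide domains could account for part of the difference, and how much stays open.

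The second pattern is that H3K27ac peaks on chromosome 8 were kept less often, 49.6% of 2967 against 64.8% elsewhere. The 70 to 110 Mb part held 1479 untreated H3K27ac peaks, of which 40.5% were retained, beside 363 untreated Pol II peaks. Narrower peaks are not the whole cause, since within quintiles of width the odds ratio was 0.581 (0.532 to 0.635). Extra DNA copies there, which might lift weak background over the threshold, stay open: the narrowest quintile of CTCF peaks was about as frequent on chromosome 8 as elsewhere (odds ratio 1.06, 0.955 to 1.17), and an effect of auxin on this region is untested.

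The third pattern is that the Pol II list grew after auxin while the H3K27ac list shrank. Whether weak peaks crossed the calling threshold stays open: 7.89% of gained Pol II peaks lay in the wider 2 quintiles of the auxin list, but so did 6.07% of gained H3K27ac and 3.97% of gained CTCF peaks, whose lists shrank. Most of the growth did not lie directly on gained H3K27ac peaks, since 485 of 8970 gained Pol II peaks (5.41%, Wilson interval 4.96 to 5.89) overlapped one. This count leaves out H3K27ac gained at a distance from the Pol II peak and any rise within listed H3K27ac peaks, so their part stays open. Whether Pol II was gained more often at gained H3K27ac peaks also stays open, with an odds ratio of 0.898 (0.792 to 1.02) within quintiles of width and 1.08 with a gap of up to 1 kb. Among auxin Pol II peaks at an auxin H3K27ac peak, 17.5% of 2769 gained peaks and 10.3% of 12748 others lay at a gained H3K27ac peak (odds ratio 1.86, 1.65 to 2.09, Fisher's exact test, p = 6.94e-25, not stratified by width). A difference in depth or enrichment between the libraries was not tested.

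SMC1 retention also differed between chromosomes, from 4.85% of 227 peaks on X to 20.5% of 776 on chromosome 10, 22.2% of 645 on chromosome 17, 22.8% of 785 on chromosome 8 and 23.8% of 122 on chromosome 21. Below 12 Mb on chromosome 21, the CTCF list went from 12 to 16 peaks and the SMC1 list from 2 to 8, against the direction of the genome. These counts are small, and both gained CTCF peaks named on chromosome 21 lie there. Whether blacklisted regions were filtered is not known, so a gain of binding there cannot be told from an artifact.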
